A study of Homo sapiens with 2 samples.

How the data were processed

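The series holds 2 samples of MCF-7, an established line of estrogen receptor-positive human breast adenocarcinoma cells: 1 chromatin immunoprecipitation (ChIP) with an antibody against ACTR5, and 1 input, the same kind of chromatin sequenced without an antibody. Per the labels' protocols, cells were fixed in formaldehyde for 10 minutes, chromatin was sheared by sonication, 10 ng of DNA entered each library, fragments of 150 to 350 bp were selected and libraries were amplified for 10 cycles. Per the submitters' processing notes, FastQC, Bowtie2, MACS2 and deepTools were used with the hg19 genome build. Versions, settings, read filters and the role of the input in peak calling are not given in the sources used here.

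Only the ACTR5 sample has a file that was analysed here. It lists peak summits, 1 bp positions of highest signal, each with a score. The deposited score is taken as −log10 of the peak caller's p or q value, the form in which MACS2 writes summit lists. The sources used here do not say which of the p and the q it is. The lowest score, 1.33, stands for a p or q of 0.0463. No peak number carries a letter, so every summit in the file is the single summit of its own peak. Peak widths, read counts, sequencing depth and the input signal are not in the list and were not used here. A score grows with both enrichment and read depth. It is used only within the list, to describe and rank summits and to compare their medians between regions. Positions are given 1-based in hg19.

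The supplied gene table is on another build (GRCh38.p14), so no summit was assigned to a gene. From it only the number of protein-coding genes on each chromosome was taken. The planned results that need an hg19 annotation or genome sequence were therefore not run: distance to transcription start sites, genomic features, position relative to the start, gene orientation, gene lists (with the named genes ACTR5, INO80, YY1 and MYC) and sequence motifs. In their place, hg19 chromosome lengths from GenomeInfoDb 1.38.1, hg19 Giemsa bands from circlize 0.4.16, and the chromosome X CpG islands distributed with pyranges 0.1.4 were used. The last band of every chromosome ended at the hg19 length. The island file does not name its build. Its last positions lay within the hg19 lengths, and shifting the X summits by 2 to 1000 kb lowered their overlap with islands from 75% to between 0.0% and 5.26%. The switch to bands, islands and gene counts was made after the list had been seen, while the summit counts, scores, clustering and the rule for named summits were set before the data were examined. That rule names the 20 summits of highest score, at most 5 from any 1 Mb bin, by position. Bands and chromosomes named in the text are those of highest or lowest density, those in the gained regions 17q23 and 20q13, and a few chosen after their values were seen, which are marked. The gained regions were fixed beforehand as the spans from the first to the last gene of a list. All bands of 17q23 and 20q13 were used in place of those spans, a choice made after the list had been seen.

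Summits per Mb carry exact Poisson 95% intervals and shares carry Wilson 95% intervals. All cover counting error only. Comparisons with chance used 1000 sets of random positions, with the same number of summits per chromosome and centromeric, variable and stalk bands left out (40 summits in those bands were left out too, leaving 5500). Sequence gaps outside those bands were not removed. A second set of 1000 drew the positions within the same band. The smallest p that 1000 sets can give is 0.001. The density of light over darkest bands was tested by 100000 permutations of stains among the bands of each chromosome, one-sided. Correlations across chromosomes and differences of median score were tested with 100000 permutations, two-sided, for which the smallest p is 1e-05. Intervals of differences of medians came from 10000 bootstrap draws. Benjamini-Hochberg adjustment covered the 8 score comparisons and, separately, the 3 comparisons of X island properties, which used 10000 sets of islands drawn in proportion to their length, two-sided. Neighbouring summits share chromatin and copy number, so tests that treat summits as independent give p-values that are too small. Alternatives kept the summits scoring at or above the median, kept 1 summit per cluster of summits under 1 kb apart, left out the densest bins, or changed distances and regions. The procedures were tested on simulated data: with 5500 positions and a light-over-darkest density ratio planted at 3, the mean ratio recovered over 20 sets was 3.04 and 20 sets passed 0.05. With a ratio of 1 the mean was 0.988 and 0 sets passed. In a set with 800 planted paired positions, 823 had a neighbour within 1 kb, against 24 before planting. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.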

Results

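The binding of ACTR5 was profiled across the genome of MCF-7 cells by ChIP-seq. ACTR5 (also called ARP5) is an actin-related subunit of INO80, an ATP-dependent complex that remodels nucleosomes at promoters and at replication forks. The series concerns transcription running against replication at sites where replication starts, and the ChIP addresses where an INO80 subunit sits on chromatin. The 2 samples are 1 ACTR5 ChIP and 1 input. There was no replicate, so no value below has an error between replicates, and intervals cover counting error only. The sequencing depth is unknown from the summit list.

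ACTR5 was called at 5559 summits, of which 5540 lay on chromosomes 1 to 22 and X. The scores, taken as −log10 of the caller's p or q, were spread over a wide range. Their median was 9.17 (95% bootstrap interval 9.08 to 9.40), their quartiles were 5.86 and 16.9, and their 90th percentile was 30.9. The highest score was 238, and 40 summits scored 100 or more. At the weak end, 19 summits scored below 2.

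The strongest summit lay in 6p21.33, at chromosome 6 position 31588618, with a score of 238. The same band, part of the major histocompatibility complex region, held the third, at position 31509638 with a score of 219. The second lay in 16p11.2 (chromosome 16, position 30709638, score 227). The fourth was in 1p31.3 (chromosome 1, position 67896003, score 195) and the fifth in 20q11.22 (chromosome 20, position 34330078, score 179). Chromosome 17 held 5 of the 20 strongest summits, where 1.34 would be its share by summit number. These were in 17q24.2 (position 65821746, score 166), 17q23.2 (position 58603326, score 159), 17q22 (position 56160682, score 156), 17q21.31 (position 43238857, score 135) and 17q23.3 (position 62501753, score 135). Chromosome 20 held 3 where its share would be 0.679, with 20q13.2 (position 52824735, score 159) and 20q13.13 (position 47538376, score 128) besides 20q11.22. Of the others, chromosome 1 also had summits in 1q23.1 (position 156737470, score 145), 1q21.3 (position 154192969, score 128) and 1p36.12 (position 21503240, score 124). Chromosome 12 had 12q24.31 (position 120933782, score 142) and 12q13.2 (position 56510522, score 137). The rest were in 2p16.1 (chromosome 2, position 55844634, score 138), 6p21.31 (chromosome 6, position 36562224, score 128) and 11q13.2 (chromosome 11, position 67980693, score 119.6). These summits were not matched to genes, for want of an annotation on the same build. Those on chromosomes 17 and 20 all lie on 17q and 20q, arms known to be gained in MCF-7. Whether copy number raised the scores of these summits was not tested.

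ACTR5 summits followed the gene content of the chromosomes. Chromosome 19, the most gene-dense, had the highest density at 5.26 summits per Mb (95% Poisson interval 4.69 to 5.88), followed by chromosome 17 at 4.57 (4.12 to 5.06). Chromosome 16 had 2.99 per Mb (2.64 to 3.37), chromosome 20 had 2.98 (2.57 to 3.44) and chromosome 12 had 2.66 (2.39 to 2.95). The gene-poor chromosomes 13, 18 and 4 had the lowest densities, at 0.721 (0.574 to 0.893), 0.756 (0.575 to 0.975) and 0.847 (0.722 to 0.989) per Mb. Across the 23 chromosomes, summits per Mb rose with protein-coding genes per Mb (Pearson's r = 0.922, permutation p = 1e-05; Spearman's rho = 0.891, permutation p = 1e-05, the smallest p the permutations can give). Without chromosomes 17 and 19, the 2 farthest from the median gene density, r was 0.830 (permutation p = 1e-05). This was the only such relation computed.

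**Figure D1:**
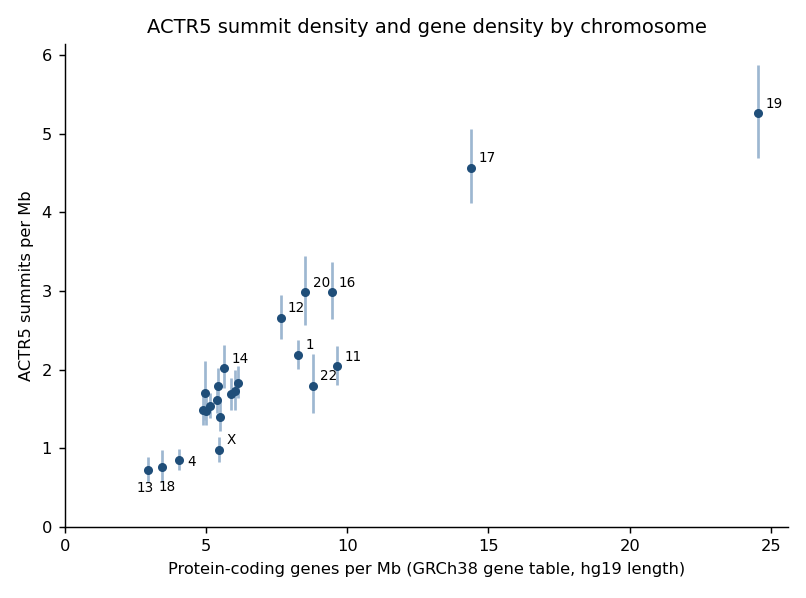
Each point is a chromosome, with protein-coding genes per Mb on the x axis, ACTR5 summits per Mb on the y axis and exact Poisson 95% intervals as bars; 13 of the 23 points are labelled. Summit density rises with gene density, from 0.721 per Mb on chromosome 13 to 5.26 per Mb on chromosome 19.

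Relative to gene number, the order of the chromosomes changed. The genome carried 27.7 summits per 100 protein-coding genes. Chromosome 19, with 21.4 (95% Poisson interval 19.1 to 24.0), lay below this value in spite of its high density per Mb, as did chromosome 11 with 21.2 (18.8 to 23.9), chromosome 4 with 21 (17.9 to 24.5), chromosome 22 with 20.4 (16.4 to 25) and chromosome X with 17.9 (15.2 to 21). Chromosomes 14, 20, 12, 10, 17 and 16 lay above it, with 35.9 (31.3 to 41.0), 35.0 (30.2 to 40.4), 34.8 (31.2 to 38.6), 33.0 (28.9 to 37.4), 31.7 (28.6 to 35.1) and 31.6 (28 to 35.6). Chromosome 21 had 34.3, with an interval of 27.3 to 42.6 that included the genome-wide value. No test was made of these differences between chromosomes.

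Within chromosomes, ACTR5 summits were concentrated in light Giemsa bands, the GC-rich, gene-rich and early-replicating part of the genome. Over all chromosomes together, light (gneg) bands held 2.72 summits per Mb (95% Poisson interval 2.63 to 2.81). The faintly stained gpos25 bands held 3.12 (2.89 to 3.36), a value not adjusted for which chromosomes carry them. The density was 1.64 (1.52 to 1.77) in gpos50, 0.989 (0.894 to 1.09) in gpos75 and 0.526 (0.464 to 0.593) in gpos100, the darkest, gene-poor and late-replicating bands. Pooled over all chromosomes, light bands were 5.17 times as dense as the darkest bands (one-sided permutation p = 1e-05, the smallest the permutations can give). None of the permutations passed a ratio of 2.02. Chromosomes without a darkest band, such as 17 and 19, entered only the light side, so differences between chromosomes are part of the ratio. The permutations kept each stain on its chromosome and so shared this feature. The direction was the same on all 18 chromosomes that have both stains. On chromosome 4 the darkest bands held 0.0243 summits per Mb against 1.56 in the light bands, and on chromosome 14 they held 1.28 against 3.19. Light bands took 63.6% of summits (95% Wilson interval 62.3 to 64.9), against 46.5% of random positions. The darkest bands took 4.76% (4.23 to 5.36), against 15.6%. Without an input signal, these comparisons do not show that the preference is particular to ACTR5.

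**Figure D2:**
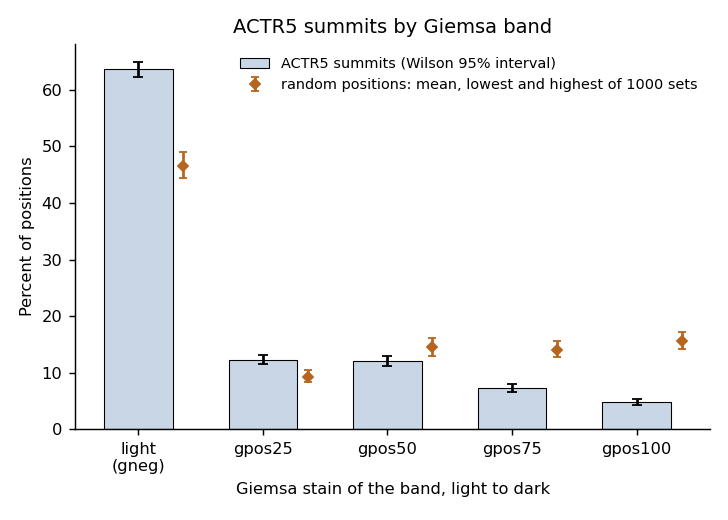
Bars give the percent of the 5500 ACTR5 summits in bands of each Giemsa stain, from light to dark, with Wilson 95% intervals; diamonds give the mean of 1000 sets of random positions on the same chromosomes, with the lowest and highest set. Summits exceed random positions in light and gpos25 bands and lie below them in gpos50, gpos75 and gpos100 bands.

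The strength of the summits did not follow the stain. The median score was 9.17 over 3499 summits in light bands and 9.15 over 262 in the darkest bands, a difference of 0.0173 (95% bootstrap interval −1.46 to 1.03; permutation test, p = 0.962, Benjamini-Hochberg adjusted p = 0.962).

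Among bands of 1 Mb or more, 11q13.1 was the densest, with 40 summits in 2.5 Mb, or 16 per Mb (95% Poisson interval 11.4 to 21.8). It was followed by 6p21.33 with 14.7 per Mb (9.52 to 21.7), 6p22.2, the band of the largest cluster of replication-dependent histone genes, with 13.9 (8.99 to 20.5), 1q21.3 with 11.9 (9.0 to 15.5) and 12q24.31 with 11.7 (8.97 to 15.1). Next were 1q22 with 10.7 per Mb (6.1 to 17.3), 16q24.2 with 10.6 (6.19 to 17) and 12q13.13, which carries keratin and HOXC genes, with 10.3 (7.17 to 14.3). At the other end, 108 of 784 bands had no summit, among them 20 of the 81 darkest bands and 47 of the 409 light bands. The longest empty bands were 13q31.1 (8.7 Mb), 4q28.3 (8.4 Mb), 10q21.1 (8.3 Mb) and 4p15.1 (8.1 Mb). The count of 0 in 13q31.1 had an exact Poisson upper bound of 0.424 summits per Mb.

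**Figure D3:**
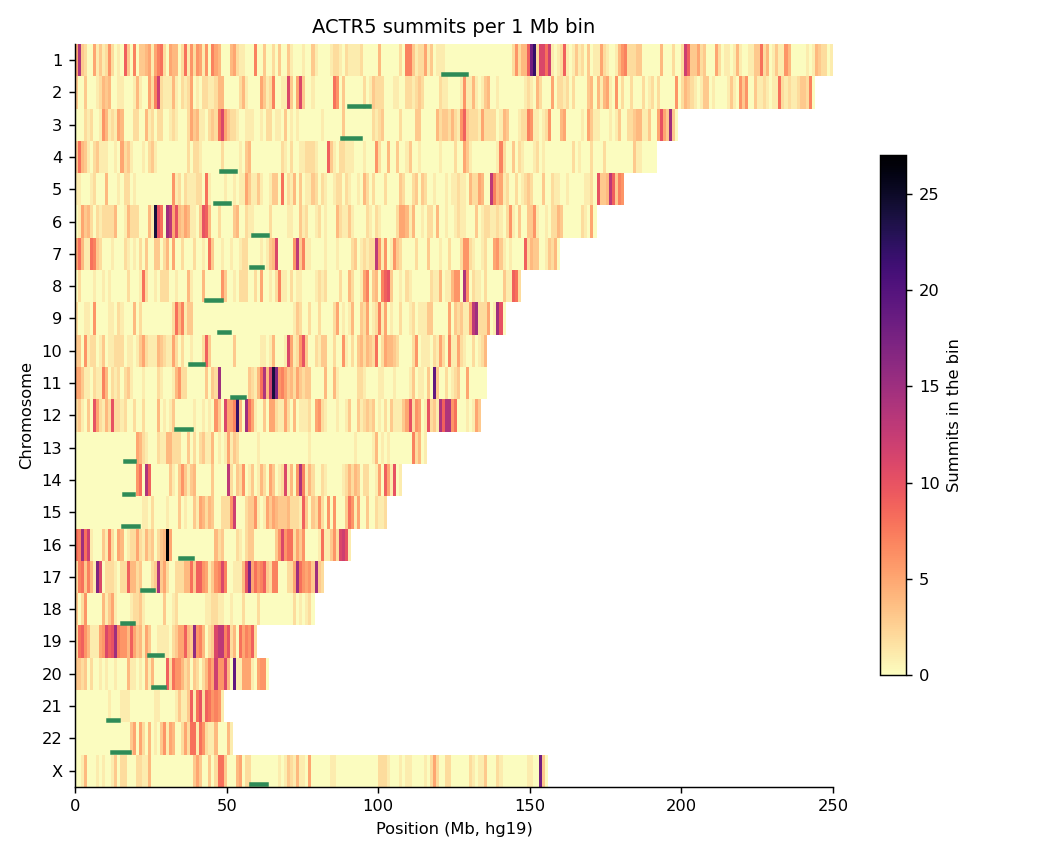
Each row is a chromosome, with position in Mb (hg19) on the x axis and the number of ACTR5 summits in each 1 Mb bin as colour; green bars mark centromeric bands. The darkest bins lie on chromosomes 1, 6, 11, 12 and 16, the highest with 27 summits, and chromosomes 4, 13 and 18 are sparse.

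On chromosome X, the only one with an island map used here, most ACTR5 summits lay in CpG islands, the CpG-rich stretches that cover many promoters. Of 152 X summits, 114 lay inside an island, or 75% (95% Wilson interval 67.6 to 81.2). Random X positions gave 0.472% on average and 3.95% at most (one-sided permutation p = 0.001, the smallest that 1000 sets can give). These positions were not matched for GC content, and no input signal was available. The comparison therefore does not show that a preference for islands is particular to ACTR5. Within 500 bp of an island the share was 83.6% (76.8 to 88.6). Of the 38 summits outside islands, 13 lay within 500 bp of one and 19 lay more than 10 kb away. Inside islands, 54 of 114 summits (47.4%, 38.4 to 56.5) lay in the middle 33.3% of the island's length, more than an even spread gives (exact binomial test, two-sided, p = 0.00198).

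A minority of the islands was occupied. Of 896 X islands, 102 held a summit, or 11.4% (95% Wilson interval 9.47 to 13.6). The occupied islands had a median length of 842 bp and 79 CpG sites, and the unoccupied ones 557 bp and 49. A position picks long islands more often by chance alone, so the occupied islands were compared with sets of 102 islands drawn in proportion to their length. Their median length was 842 bp against 924 bp in those sets (95% of sets 797 to 1017 bp; permutation p = 0.218, adjusted p = 0.327), and their median number of CpG sites was 79 against 80.5 (70.5 to 95.5; permutation p = 0.558, adjusted p = 0.558). Neither difference passed the test. The CpG sites of occupied islands were slightly denser, with 9.24 per 100 bp against 8.68 (8.35 to 9.03; permutation p = 0.0018, adjusted p = 0.0054). The strongest X summit, in Xp11.23 at position 47093300 with a score of 116, lay in an island of 65 CpG sites from 47092560 to 47093306. The second, in Xq28 at position 153236889 with a score of 99.2, lay in an island of 237 CpG sites from 153236072 to 153238480. The median score was 11.5 inside islands and 7.48 outside, a difference of 4.07 that did not pass the test (95% bootstrap interval −0.516 to 6.63; permutation test, p = 0.0692, adjusted p = 0.0923).

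**Figure D4:**
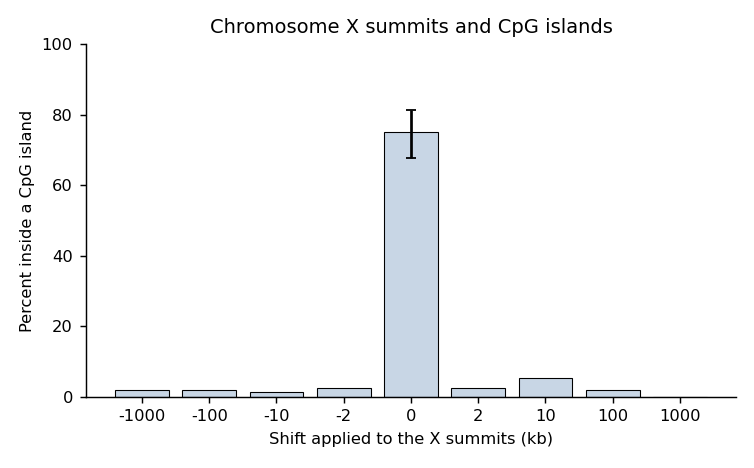
Bars give the percent of the 152 chromosome X summits inside a CpG island at their called position (shift of 0 kb, with its Wilson 95% interval) and after shifting all of them by the distance on the x axis. The share is 75% at the called position and at most 5.26% after a shift of 2 kb or more.

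ACTR5 summits lay close to one another. Of 5500 summits, 29.9% had a neighbour within 10 kb, against 4.71% on average (highest 5.95%) for random positions on the same chromosomes and 7.42% (highest 8.75%) for random positions within the same bands (permutation p = 0.001 for both, the smallest possible). The median distance to the nearest summit was 46.9 kb, against 157 kb and 107 kb. The excess was greatest at short range: 509 neighbouring pairs lay under 1 kb apart, where within-band random sets gave 21.5 on average and 36 at most. Their median distance was 608 bp (quartiles 500 and 757 bp), and 58.3% of them were 400 to 700 bp apart. Each summit belongs to its own peak, so peak widths, which are not in the list, limit how close neighbours can be. Random positions have no such limit. Between 2 and 5 kb there were 96 pairs, against a mean of 63.7 and at most 86. On chromosome X, 10 of the 12 pairs under 1 kb apart had both summits in 1 CpG island.

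**Figure D5:**
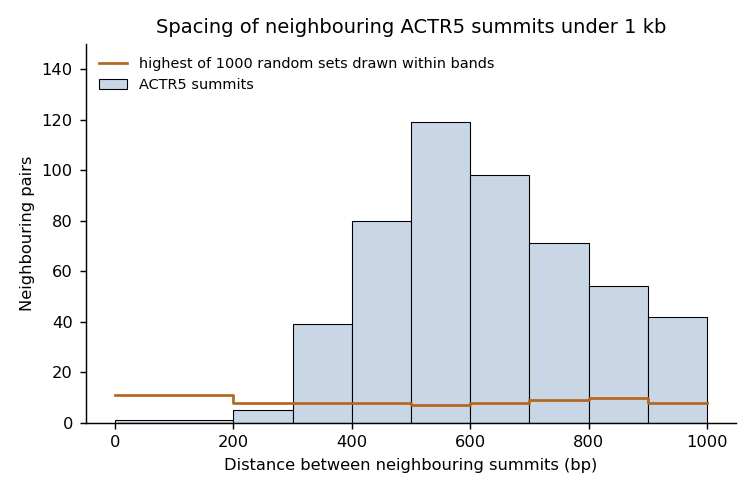
Bars count neighbouring ACTR5 summit pairs by their distance in bp, in steps of 100 bp after a first bar of 200 bp, for distances under 1 kb; the line is the highest count of 1000 random sets drawn within bands. The counts reach 119 between 500 and 600 bp and 1 under 200 bp. Peak widths limit short distances between summits but not between random positions.

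At the scale of 1 Mb, 5 bins held more summits than any bin of the chromosome-wide random sets, whose highest held 19. They were 30 to 31 Mb of chromosome 16 in 16p11.2 with 27 summits (95% Poisson interval 17.8 to 39.3), 26 to 27 Mb of chromosome 6 in 6p22.2 with 24 (15.4 to 35.7), 65 to 66 Mb of chromosome 11 in 11q13.1 with 24 (15.4 to 35.7), 151 to 152 Mb of chromosome 1 in 1q21.3 with 22 (13.8 to 33.3), and 53 to 54 Mb of chromosome 12 in 12q13.13 with 22 (13.8 to 33.3). Together they held 119 summits, 2.16% of the total in 0.178% of the length. With only summits scoring at or above the median, 0 bins passed the highest chromosome-wide random bin. Against the within-band sets, the densest bin, with 27 summits, was above their mean highest bin of 19 (permutation p = 0.003), but no bin passed the highest, which held 28.

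The regions 17q23 and 20q13, taken as whole bands and both known as gained in MCF-7, held more summits than their length. Together they had 153 summits, 2.97 times their share of the length (95% Poisson interval 2.52 to 3.48). The ratio was 4.29 (3.10 to 5.81) for 17q23 and 2.66 (2.19 to 3.20) for 20q13. These ratios are to the genome as a whole. The arms that hold the regions were dense too, with 4.98 summits per Mb (4.41 to 5.61) on 17q and 4.64 (3.94 to 5.43) on 20q. Light bands genome-wide had 2.72. Of the 156 summits on 20q, 111 lay in 20q13. Whether either region exceeded the rest of its arm was not tested. Within 17q23, 17q23.1 had 17.1 summits per Mb (8.86 to 29.9), 17q23.2 had 6.43 (3.81 to 10.2) and 17q23.3 had 8.0 (4.13 to 14), with median scores of 20.9, 22.1 and 14. In 20q13, 20q13.13 had 8.24 summits per Mb (5.47 to 11.9) and 20q13.2 had 4.81 (3.1 to 7.1), with median scores of 12.2 and 8.91, the latter below the genome-wide median of 9.17. In light bands the median score was 12.9 over 79 summits in the combined regions and 9.14 over 3420 summits elsewhere. The difference was 3.74 (95% bootstrap interval 1.39 to 9.02; permutation test, p = 0.00208, adjusted p = 0.00832). Taken alone, 17q23 differed by 9.55 (interval −0.0981 to 22; permutation test, p = 0.00064, adjusted p = 0.00512) and 20q13 by 2.37 (interval 0.734 to 6.84; permutation test, p = 0.0562, adjusted p = 0.0899), which did not pass the test.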

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

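All tests in this part were chosen after the summit list had been seen, as were the within-band draws they use. For 3 of them, the ratio to stain and the tests of neighbours within 10 kb and at 10 to 100 kb within bands, the outcome was still unknown when they were written down.

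Outside the nuclear chromosomes, 7 summits lay on the mitochondrial genome of 16.6 kb, with a median score of 28.1 (11 to 75.4). The unplaced contig gl000220, which carries ribosomal DNA sequence, held 6 summits with a median score of 4.59 (2.58 to 5.63). Both are present in many copies per cell, neither entered a comparison, and no expected number of calls was available to set beside them, in the absence of an input signal. They are given as values from outside the compared chromosomes, where 19 summits lay in all. The remainder were on other contigs, except 1 on chromosome Y.

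The first pattern weighed is the excess of summits in 17q23 and 20q13. The tables argue against the general richness of light bands as the whole cause, since the regions held 2.73 times the number expected from the genome-wide density of each stain (95% Poisson interval 2.32 to 3.20). That number makes no allowance for the density of the whole arms, 4.98 summits per Mb on 17q and 4.64 on 20q. The excess over the genome is therefore not shown to be particular to these regions. A gain in copy number may contribute, since more template can raise both the chance of a call and its score. How far the caller corrected for this is not known. The median score in light bands was 3.74 higher there than elsewhere, and 17q23, with a median of 18.7 over 24 summits, differed most. The interval for 17q23 alone reached −0.0981. The difference for 20q13 alone, 2.37, did not pass the test (permutation test, adjusted p = 0.0899). A local richness in genes or strong promoters beyond the stain stays open and would give the same values, because no gene annotation on this build was used and no input signal was available.

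The second pattern is the short spacing of summits. Differences of density between whole bands are argued against as its whole cause, since 29.9% of summits had a neighbour within 10 kb and the highest within-band random set had 8.75%. They may account for a part, as drawing within bands raised the random mean from 4.71% to 7.42%. Wide enriched regions split into several peaks could make the pairs near 600 bp. After keeping 1 summit per 2 kb, 9.05% of 4818 summits still had a neighbour within 10 kb, against 6.28% on average and 8.01% at most within bands, which speaks against splitting only for regions narrower than 2 kb. A split region and separate binding sites cannot be told apart without peak widths or read profiles: a further test, the share with the nearest neighbour at 10 to 100 kb (35.2%, against 37.7 to 43.4% in within-band sets), is lowered by the pairs themselves and so decides nothing.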

How the results depend on the processing

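Of 53 alternative values, 48 kept their direction and their side of the threshold, or stayed within 1.5 times a count, and 0 reversed. Of the 48, 23 were repeats of the light-over-darkest ratio with 1 chromosome left out. Those repeats share most of their data and are not separate support. The remaining 5 of the 53 values moved. Keeping summits at or above the median score left 2783 summits with a median score of 16.9, both by construction, and 0 bins above the highest random bin in place of 5, where the cause was not tested. Against random positions within bands, 0 bins stood above the highest random bin with all summits kept, since the highest bin of those sets held 28, although the densest bin of 27 exceeded the highest bin of most sets (permutation p = 0.003). Keeping 1 summit per cluster under 1 kb raised the median score to 9.89, since the highest of each cluster was kept. That setting lowered the excess of neighbours within 10 kb from 6.34 to 3.48 times random, and drawing random positions within bands lowered it to 4.03 times. Leaving out each chromosome in turn gave light-over-darkest ratios of 4.89 to 5.61. The alternatives for bands, islands and gene density, the within-band draws and the use of 17q23 or 20q13 alone were chosen after seeing the data. The settings listed beforehand for start sites, features, gene lists, gene orientation and motifs were not run, for want of an annotation on the build of the list. No paired analysis was possible because the list comes from 1 library. With 1 library, no replicate could be left out. The depth is unknown, so how many weaker sites were missed cannot be stated.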

Other observations

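Some bands were looked at because of what they are known to carry, after their values were seen. The band 8q24.21, which holds MYC, had 22 summits, or 5.24 per Mb (95% Poisson interval 3.28 to 7.93), although it is of intermediate stain, where the genome-wide density was 1.64. The band 6q25.1, which holds the estrogen receptor gene ESR1, had 13 summits, or 3.71 per Mb (1.98 to 6.35), with the genome-wide value for its light stain, 2.72, inside that interval. The band 9p21.3, which holds CDKN2A, a gene lost in MCF-7, had 2 summits in 5.7 Mb, or 0.351 per Mb (0.0425 to 1.27), with the genome-wide value for its stain, 0.526, inside that interval. The variable band 19p12, rich in zinc finger genes, had 16 summits in 4.4 Mb, or 3.64 per Mb, and was left out of the comparisons by stain. None of these summits was matched to the gene named.

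Across the 509 pairs under 1 kb apart, no relation between the scores of the neighbours was detected: Spearman's rho was 0.0657 (95% bootstrap interval −0.0194 to 0.152; permutation p = 0.134). The median score was 8.09 over the 980 summits in such pairs and 9.53 over the 4520 others, a difference that was not tested.

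On some chromosomes the arms differed in density. Those named here were picked after their values were seen. Their densities were not adjusted for stain, gene content or copy number, and in MCF-7 20q is known to be gained and 18q lost. The long arm of chromosome 20 had 4.64 summits per Mb (95% Poisson interval 3.94 to 5.43) and its short arm 1.21 (0.823 to 1.72). On chromosome 8 the long arm had 1.85 (1.59 to 2.14) and the short arm 0.812 (0.566 to 1.13). On chromosome 18 the long arm had 0.559 (0.385 to 0.784) and the short arm 1.62 (1.1 to 2.40). On chromosome 6 the short arm had 3.19 (2.75 to 3.68) and the long arm 1.17 (0.974 to 1.39). On others the intervals of the 2 arms overlapped, as on chromosome 19 with 6.25 (5.2 to 7.45) and 6.21 (5.3 to 7.23), chromosome 17 with 4.19 (3.38 to 5.13) and 4.98 (4.41 to 5.61) and chromosome 10 with 1.71 (1.32 to 2.18) and 1.89 (1.62 to 2.19), short arm first.

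A hypothesis written before the arms were compared was that copy number in MCF-7 may shape the scores, with higher scores on 1q, 17q and 20q, known to be gained, and lower scores on 9p and 18q, known to be lost. In light bands the median score was 1.03 higher on 1q, 17q and 20q than on the other arms (95% bootstrap interval 0.0955 to 2.09; permutation test, p = 0.015, adjusted p = 0.0399). Without 17q23 and 20q13, in a test added after seeing the data, the difference no longer passed, at 0.731 over 372 in place of 451 summits (interval −0.188 to 1.71; permutation test, p = 0.179, adjusted p = 0.205). By arm, the medians were 9.56 on 1q, 10.5 on 17q and 10.2 on 20q, against 9.09 over the other arms together. Single arms outside 1q, 17q and 20q ranged from 6.55 on 9p to 11.3 on 3p, so high scores were not particular to the gained arms. On 9p and 18q the median was 6.75 over 61 summits against 9.12, a difference of −2.37 (interval −3.51 to −0.922; permutation test, p = 0.0524, adjusted p = 0.0899), which leaves the part on lost arms open. The arm 8p, outside that set, had a median of 6.72, against 6.55 on 9p and 6.82 on 18q.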
